A study of Mus musculus with 12 samples.

How the data were processed

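Total RNA of 12 hepatocyte cultures was labelled with Cy3 and hybridized by the authors to 1-colour Agilent whole mouse genome arrays, 4 to a slide on 3 slides. Scans at 5 micron were read with Feature Extraction 10.1.1.1, all on 1 scan day. The deposited array files hold, per the file headers, the processed signal of each spot as an intensity on a linear scale, background-subtracted within the array and not normalized between arrays. They also give the median intensity of the spot and of its background, and other columns with flags of 0 or 1 for spots well above background, non-uniform, outlying or saturated. The deposited table of all arrays holds log2 values, which the authors made by setting signals below 1 to 1 and by quantile normalization. It was compared with values recomputed from the array files, and the correlation per array was at least 0.99997. The authors name limma without a version.

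Values were recomputed from the array files. Of 43379 spots that are not controls, those with a non-uniformity or outlier flag (74 to 206 per array) were set to missing, and no spot was saturated. Signals were floored at 1, spots of a probe were averaged, and the log2 values were quantile normalized. A probe was tested if it was well above background on all 3 arrays of at least 1 group and had 2 or more values in every group, which left 24963 of 41174 probes. The files pair no probe with a gene symbol, so symbols were taken through RefSeq accessions from an annotation of assembly GRCm38.p6, used for names and for which chromosome a gene shares with another, not for coordinates, since the array files name another build. Of the probes 24375 matched and 16799 did not, and the latter are named by their accession or probe name. A gene is represented by its brightest tested probe, which gave 19018 genes or accessions, 12795 of them named and 4754 with more than 1 tested probe. Between 22706 and 25656 probes per array were well above background in +/+ control cells, 23354 to 25339 in +/+ shTLS cells, 25148 to 25921 in -/- control cells and 25119 to 26680 in -/- shTLS cells. Replicates of a group had correlations of 0.925 to 0.972, and 0 pairs of arrays were identical (highest correlation 0.989). The first 3 principal components held 40.1%, 21.7% and 11.4% of the variance.

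Tests were done with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with 1 fit of the 4 group means to all 12 arrays (8 residual degrees of freedom, prior degrees of freedom 2.82) and moderated two-sided tests. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. Comparisons were shTLS against control in each genotype and averaged over both, -/- against +/+ with each vector and averaged over both, and the difference between both effects of shTLS. The comparison of genotypes averaged over vectors took the mouse as a random block (correlation within mice 0.584), since both arrays of a mouse are not independent. The source names give the mouse and the independent assay. Deviations from the group mean were compared in the 4 pairs of groups that share a genotype or a vector. They correlated by 0.233 to 0.675 between arrays of the same number and by at most 0.0970 between arrays of different numbers. Deviations within a group add up to 0, so the low values follow in part from the high ones. The number, which is also the slide, and the mouse were each used as a block as an alternative. With 3 against 3 arrays an exact test of a single gene cannot go below a two-sided p of 0.1.

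The sets of genes consisted of 25 lists with 610 genes, of which 568 were measured, 8 of them under another symbol. The lists cover antioxidant and mitochondrial redox defence, glutathione transferases, gluconeogenesis, fatty acid oxidation, oxidative phosphorylation, the tricarboxylic acid cycle, regulators of mitochondrial biogenesis, cholesterol synthesis and fatty acid synthesis. They further cover the interferon response, inflammation and the acute phase, the unfolded protein and integrated stress response, heat shock chaperones, p53 targets, cell cycle, circadian clock, haem metabolism, FET proteins and heterogeneous nuclear ribonucleoproteins, xenobiotic cytochromes, bile acids and hepatocyte identity. The last 4 hold markers of macrophages, endothelial cells, stellate cells and cholangiocytes. One gene is shared by 2 lists. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 25 lists of a comparison, and beside it with an estimated correlation and with fry. Results of fry for single lists are not given here and enter only the counts of alternative values. Members were also adjusted over the list alone.

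The comparisons, lists, tests, filters and the rule for named genes were fixed before the data were examined. Ppargc1a is always named. Among called genes with a symbol and the same sign in all 3 pairs, the 10 largest rises and 10 largest falls are named (5 and 5 for averaged comparisons and the difference of effects). Where fewer than 10 pass, the 10 with the smallest p are named and said not to pass. Up to 4 members with the smallest p are named for lists that pass or hold 3 or more called genes, and the antioxidant list is always described. Other genes named for a count of 5 or fewer were chosen after their values were seen. These are Il6 and, among lists that did not pass, the called members. Some genes that the rule takes are not reported here.

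Alternatives were 75th percentile scaling, normexp background correction with an offset of 50, the deposited values, no filter on dim probes, a filter for all arrays, outlier spots kept, the mean of a gene's probes, limma's trend and robust options, a fold of at least 1.5, the replicate, slide and mouse blocks, a fit to only the groups compared, and each array left out in turn. The median signal stood in for the mean signal in normexp, since the files give no mean. Scaling to 320 spike-in control spots per array, whose mean log2 signal was 10.74 to 11.38, and the block without the arrays of 1 number were chosen after seeing the data. The pipeline was tested on simulated data with 100 genes of 18930 changed by each size. It recovered 49% of 4-fold and 3% of 2-fold changes for shTLS in +/+ cells, 35% and 0% in -/- cells, and 78% and 24% averaged over genotypes. For genotype it recovered 45% and 6% with the control hairpin, 43% and 1% with shTLS, and 61% and 9% averaged over vectors. With the replicate block the last of these gave 177 false calls of 300, and that block is given there as an alternative. The simulated noise was shared by the arrays of a mouse and not by those of a replicate number, which correlated in the data. The recovered shares and the false calls may therefore differ in the data. All 12 arrays were used.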

Results

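Gene expression was measured in primary hepatocytes of C57BL/6 mice that carried PGC-1alpha (+/+) or lacked it (-/-). PGC-1alpha, encoded by Ppargc1a, is a transcriptional coactivator of mitochondrial and gluconeogenic genes. The cells received an adenovirus with a short hairpin RNA against TLS (shTLS) or a control short hairpin RNA. TLS is an RNA-binding protein. Infection was at a multiplicity of 5, in medium with 100 nM dexamethasone and 100 nM insulin, and RNA was taken 24 h later. Each of the 6 mice, 3 per genotype, gave 1 culture per vector, so that the 4 groups held 3 arrays each. The 4 arrays of a replicate number shared a slide, on which each group always held the same position, so position and group cannot be told apart. Between 22706 and 26680 of 41174 probes per array were well above background. The 75th percentile of the processed signal was 810.4 to 1064 on the 6 control arrays and 344 to 635 on the 6 shTLS arrays. The number of arrays limits the precision of all values.

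Ppargc1a, the gene disrupted in -/- mice, had 1 probe, which read 9.22 ± 1.08 in +/+ and 9.38 ± 0.33 in -/- cells with the control hairpin, and 9.32 ± 1.44 and 8.81 ± 0.11 with shTLS (SD, n = 3). The log2 difference between genotypes was 0.16 (SE 0.67, adjusted p = 1.0) and -0.51 (adjusted p = 0.999), and it was -0.32 without the third +/+ control array and 0.32 without +/+ shTLS array 2. The labels do not say which part of the gene is deleted, so this probe checks nothing about the genotype.

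**Figure D1:**
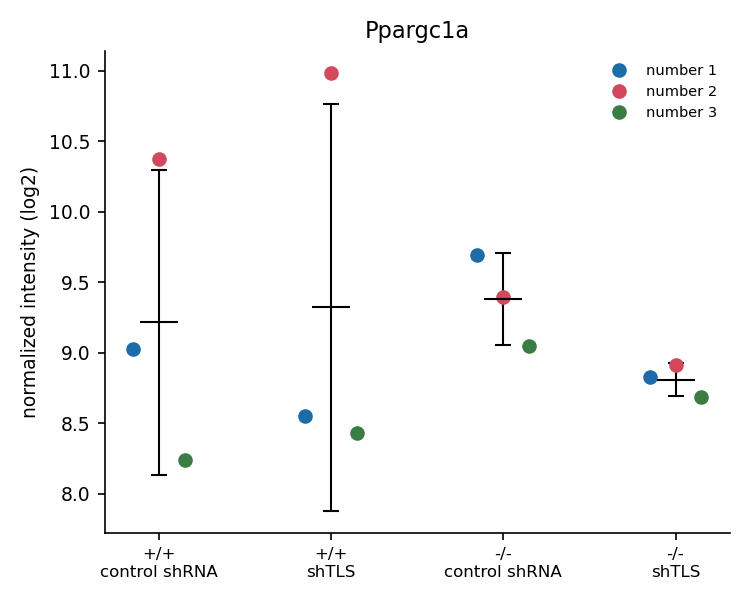
Normalized log2 intensity of the Ppargc1a probe on each array, by group (points, coloured by replicate number; lines are means and bars SD, n = 3). The probe differs between genotypes by 0.16 with the control hairpin and by -0.51 with shTLS.

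The first comparison asked what shTLS changes in +/+ hepatocytes. Interferon response genes had positive differences in 26 of 30 members, and negative differences were found in all 17 glutathione transferases, 19 of 24 cholesterol synthesis genes and 17 of 18 fatty acid synthesis genes. These lists passed with a preset correlation and not with an estimated one (adjusted p = 0.761, 0.584, 0.761 and 0.220 with an estimated correlation), and none of their members passed over all genes, against 8, 2, 2 and 2 with the block. For the last 3 lists that share was no larger than the share of all genes with the block (2408 of 19018). Single genes rose far more, among them Sox12, a transcription factor of the SRY-related family, and Xcr1, a chemokine receptor of dendritic cells (59.2-fold). Il6, an inflammatory cytokine, rose by 3.54 on the log2 scale (SE 0.65, adjusted p = 0.0247, n = 3 arrays per group, not paired in the fit). In all, 230 of 19018 genes passed, 197 higher and 33 lower, and 3146 had an unadjusted p under 0.05. Fewer passed with normexp, with the filter for all arrays and with only the groups compared, as given below. With the replicate number as a block 2408 passed, 1438 higher and 970 lower, and 2988 with the mouse as a block. The split turned with the scaling: 85.7% of the calls were higher in the quantile-normalized data, and 7.46% of 3204 when arrays were scaled to the spike-in controls. Scaled in that way, the median of all genes shifted by -0.80 in +/+ and -0.74 in -/- cells, so the directions given for shTLS are relative to the array as a whole. The count was 112 without the first +/+ control array, 123 without +/+ shTLS array 2 and 118 without +/+ shTLS array 3.

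Sox12 had the largest rise, 9.48 (SE 1.33, adjusted p = 0.00562), with pairs of 11.3, 10.9 and 6.27. Olfr738, an olfactory receptor, rose by 6.05 (SE 0.70), Fndc8 by 5.96 and Xcr1 by 5.89 (SE 0.51, adjusted p = 0.000333). Rises of 5.36 to 5.81 were found for Unc5d, a netrin receptor, Arl10, Asb7, Adprhl1 and Terc, the RNA component of telomerase. Fndc8, Unc5d and Arl10 were above background on 1 of 3 control arrays each. Il12rb2, a subunit of the interleukin-12 receptor, was at least 6.71-fold higher (adjusted p = 1.28e-05). Each such bound is the mean of the bright group against the floor per array of the group in which the gene was not above background. The other probe of Asb7, above background on 10 of 12 arrays, gave -1.13 averaged over genotypes, and those of Xcr1 and Unc5d were above background on 0 arrays. Among the falls, Entpd8, a nucleotide-hydrolysing ectoenzyme, was at least 6.57-fold lower, Mmp24, a membrane-type metalloproteinase, at least 2.10-fold and Zbed3 at least 2.27-fold. Lrp11 fell by 2.25 (SE 0.38), Apbb1 (above background on 1 of 3 shTLS arrays) by 2.01 and Nprl3, an inhibitor of mTORC1 signalling, by 1.90 (SE 0.29). Knl1, a kinetochore protein, fell by 1.90 and Glyat, a mitochondrial glycine acyltransferase, by 1.84. Of these 18 calls, 11 were kept with each array left out in turn, 7 with only the groups compared and 12 under all the other ways of processing.

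Interferon response genes had positive differences in 26 of 30 members, with a median of 0.72 that was -0.13 when scaled to the spike-ins (pairs 0.81, 1.29 and 0.36, adjusted p = 0.000247). The call was lost with an estimated correlation (adjusted p = 0.761) and without +/+ shTLS array 1 (0.0671). No member passed over all genes, 4 passed adjusted over the list alone and 8 with the block. Rsad2, the antiviral protein viperin, read 2.38 (SE 0.51, adjusted p = 0.0538), Cxcl10 2.33, Isg15, a ubiquitin-like modifier, 2.26 and Eif2ak2 1.42. All 17 glutathione transferases had negative differences (median -0.70, pairs -1.19, -0.58 and -0.49, adjusted p = 0.000247, and adjusted p = 0.584 with an estimated correlation). None passed alone and 2 with the block, and Gsta4 read -1.30, Gstm4 -1.21 and Mgst1 -0.78. Cholesterol synthesis genes had negative differences in 19 of 24 members (median -0.36, pairs -0.86, -0.18 and -0.42, adjusted p = 0.00309). That call too was lost with an estimated correlation (adjusted p = 0.761) and without +/+ shTLS array 1 (0.0809), and 2 members passed adjusted over the list alone and 2 over all genes with the block. Srebf2, the master transcription factor of the pathway, read -1.35 (SE 0.35) and Pmvk -0.82. In fatty acid synthesis 17 of 18 members were negative (median -0.50, pairs -0.59, -0.32 and -0.61, adjusted p = 0.00916, and adjusted p = 0.220 with an estimated correlation). The call was lost without +/+ shTLS array 1 (0.0531). Srebf1 read -0.78, Gpam -1.10, Agpat2 -0.86 and Fads1 -0.77, none of them past the test without the block, which gave 2 calls in the list.

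Antioxidant genes, a group known to respond to PGC-1alpha, had a median of -0.31 with 19 of 25 members negative (pairs -0.30, -0.25 and -0.51, adjusted p = 0.0262). The call was lost with an estimated correlation (adjusted p = 0.584), with scaling to the 75th percentile (0.131) or the spike-ins (0.0895), and without the second +/+ control array (0.0699) or +/+ shTLS array 1 (0.0809). Txnrd2, the mitochondrial thioredoxin reductase, read -1.24 (SE 0.27, adjusted p = 0.0620, and 0.0142 with the block) and was the 1 member that passed adjusted over the list alone. Mt1, a metallothionein, read -1.26, Prdx2 -0.70 and Prdx3, a mitochondrial peroxiredoxin, -0.52. Targets of p53 had a median of 0.41, which was -0.40 when scaled to the spike-ins, with 18 of 25 members positive (pairs 0.19, 0.18 and 0.42, adjusted p = 0.0458). This call was lost with an estimated correlation (adjusted p = 0.495), with the block (0.0591), with 75th percentile scaling (0.0552) and without the third +/+ control array (0.0590), +/+ shTLS array 1 (0.0671) or 3 (0.111). Bbc3, the apoptosis effector Puma, read 1.01, Plk2 1.00, Polk 1.02 and Fas 0.82, the last -0.038 when scaled to the spike-ins. None passed over all genes, and with the block 4 of 25 members did, among them Bbc3 (0.0197) and Plk2 (0.0418), against 2408 of all 19018 genes. The other 19 lists gave adjusted p from 0.0742 to 0.876.

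**Figure D2:**
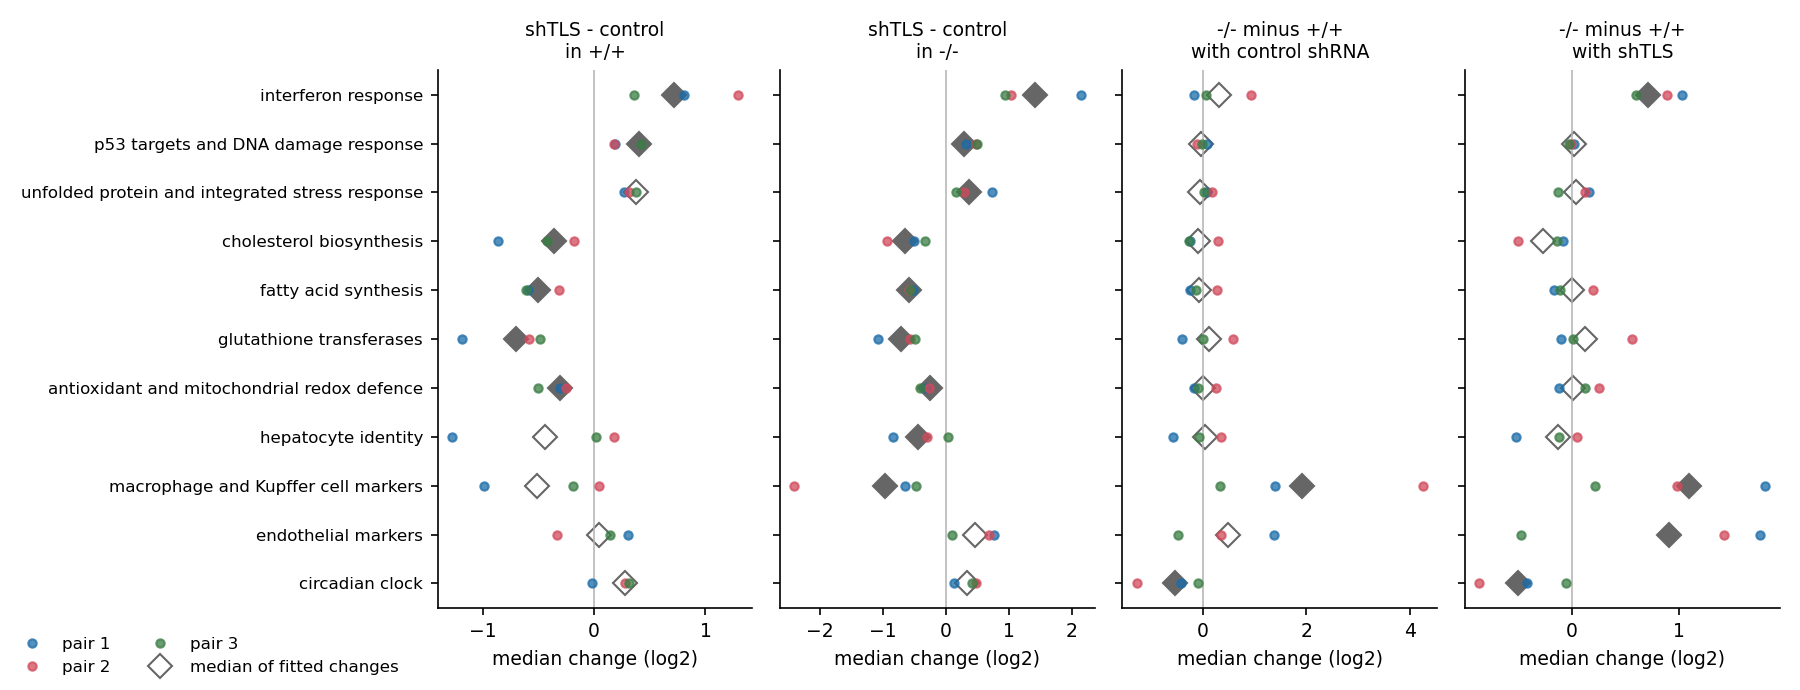
Median log2 difference over the members of 11 gene lists in 4 comparisons (points, 1 per pair of arrays with the same number; diamonds, median of the fitted differences, filled where the set test with a preset correlation gave an adjusted p under 0.05). Interferon response genes lie higher with shTLS in both genotypes, with medians of 0.72 and 1.42 (-0.13 in +/+ cells when scaled to the spike-ins), and glutathione transferases lie lower, with -0.70 and -0.71. With an estimated correlation none of these passed (adjusted p = 0.761 and 0.440 for the former, 0.584 and 0.440 for the latter).

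The same question was asked in -/- hepatocytes. Differences were positive in 29 of 30 interferon response genes and negative in all 17 glutathione transferases and 20 of 24 cholesterol synthesis genes. These lists passed with a preset correlation and not with an estimated one (adjusted p = 0.440 for each with an estimated correlation), and 1 of their members, Rsad2, passed over all genes, against 13, 1 and 3 with the block. For the transferases that share was no larger than the share of all genes with the block (1192 of 19018), while the other lists exceeded it. Sox12, Xcr1 and the other 8 genes named for their rise in +/+ cells rose here too. Of 19018 genes 183 passed, 175 higher and 8 lower, and 2309 had an unadjusted p under 0.05. With the replicate block 1192 passed, 835 higher and 357 lower, and 1624 with the mouse as a block. Calls were 95.6% higher in the quantile-normalized data and 60.8% of 194 when scaled to the spike-ins. Their number was 106 without the first -/- control array, 115 without the second, 94 without -/- shTLS array 2 and 114 without -/- shTLS array 3.

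Sox12 rose by 9.17 (SE 1.33, pairs 11.3, 9.03 and 7.15, adjusted p = 0.00608), Olfr738 by 6.11, Xcr1 by 6.00 (64.1-fold) and Asb7 by 5.97. Adprhl1 rose by 5.60, Arl10 by 5.54, Unc5d by 5.52 and Terc by 5.40, with Arl10 and Unc5d above background on 2 of 3 control arrays. Fndc8 was at least 54.7-fold higher and Il12rb2 at least 11.7-fold higher (adjusted p = 6.91e-06). The limits given above for the other probes of Asb7, Xcr1 and Unc5d hold here too. Nprl3 fell by 1.82 (SE 0.29) and Plpp2, a lipid phosphatase, by 1.44 (SE 0.24). Of these 12 calls 9 were kept with each array left out in turn and 10 with only the groups compared.

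Interferon response genes had a median of 1.42 (pairs 2.14, 1.04 and 0.95, adjusted p = 2.09e-11, and adjusted p = 0.440 with an estimated correlation). Rsad2 rose by 2.52 (SE 0.51, adjusted p = 0.0468), the 1 member past the test over all genes, while 11 passed adjusted over the list alone and 13 with the block. Isg15 read 2.24, Usp18, an inhibitor of interferon signalling, 1.71 and Eif2ak2 1.51. Glutathione transferases had a median of -0.71 (pairs -1.07, -0.56 and -0.49, adjusted p = 0.000206), cholesterol synthesis genes -0.64 (pairs -0.50, -0.94 and -0.33, adjusted p = 6.58e-05), and fatty acid synthesis genes -0.58 with 15 of 18 negative (pairs -0.52, -0.58 and -0.57, adjusted p = 0.00647). None of these calls held with an estimated correlation (adjusted p = 0.440, 0.440 and 0.188). Srebf2 read -1.24 and Hsd17b7 -1.03, and 5 cholesterol genes passed adjusted over the list alone. Gsta4 read -1.28, Mgst3 -0.95, Agpat2 -0.76 and Fasn, the fatty acid synthase, -0.60. Antioxidant genes had a median of -0.25, 18 of 25 negative (pairs -0.31, -0.27 and -0.41, adjusted p = 0.0321). That call was lost with an estimated correlation (adjusted p = 0.440), with 75th percentile scaling (0.0976), with the spike-ins (0.0607), and without -/- control array 2 (0.263) or 3 (0.0608) or -/- shTLS array 1 (0.238). Txnrd2 read -0.89, Gclc -0.85 and Prdx2 -0.66.

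Genes of the unfolded protein and integrated stress response had a median of 0.38 that was -0.32 when scaled to the spike-ins, with 24 of 29 positive (pairs 0.74, 0.30 and 0.16, adjusted p = 0.0197, and adjusted p = 0.676 with an estimated correlation). The call was lost without the first -/- control array (0.167) and without -/- shTLS array 1 (0.0541) or 2 (0.0526). Atf3 read 1.51, and Creld2 0.67, Herpud1 0.64 and Asns 0.61, which were -0.049, -0.055 and -0.018 when scaled to the spike-ins. Targets of p53 had a median of 0.29, or -0.44 when scaled to the spike-ins (18 of 25 positive, pairs 0.32, 0.48 and 0.50, adjusted p = 0.0109, and adjusted p = 0.246 with an estimated correlation). Pmaip1, the apoptosis effector Noxa, read 1.45, Polk 1.24, Plk2 1.00 and Bbc3 0.85, of which only Polk passed with the block (0.0398). Hepatocyte identity genes had a median of -0.44 with 24 of 29 negative (pairs -0.83, -0.30 and 0.04, adjusted p = 0.0197, and adjusted p = 0.676 with an estimated correlation). This call was lost without the first -/- control array (0.0931), without -/- shTLS array 1 (0.195) and with the spike-ins (0.200). Cebpa, a liver transcription factor, read -1.17, Fah -1.19 and Ass1 -0.51, against 1.01 for Asgr1. Markers of macrophages and Kupffer cells had a median of -0.96, all 18 negative (pairs -0.65, -2.40 and -0.47, adjusted p = 0.00721, and adjusted p = 0.676 with an estimated correlation). The call was lost without -/- control array 1 (0.0646) or 2 (0.198), without -/- shTLS array 3 (0.109) and with the spike-ins (0.532). Cd5l read -2.69 (SE 1.38), Marco -2.65, Cd14 -0.99 and Lyz2 -0.92. The other 16 lists gave adjusted p from 0.0592 to 0.840.

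Averaged over both genotypes, which draws on 6 mice, the effect of shTLS passed for 1553 genes, 962 higher and 591 lower (5342 with an unadjusted p under 0.05). This fit compared group means and did not pair the arrays. In the interferon list 9 of 30 members rose, and 6 of 24 cholesterol synthesis genes, 2 of 18 fatty acid synthesis genes and 2 of 17 glutathione transferases fell. The lists passed with a preset correlation and not with an estimated one (adjusted p = 0.588, 0.535, 0.165 and 0.523 with an estimated correlation), and with the block 22, 10, 6 and 8 members passed in these directions. With the block 5512 genes passed, 2915 higher and 2597 lower, and 6253 with the mouse as a block. Calls were 61.9% higher in the quantile-normalized data, with 1531 of 2010 higher under 75th percentile scaling and 650 of 9866 higher under spike-in scaling, where the median of all genes was -0.77. The count was 799 without the first +/+ control array, 675 without +/+ shTLS array 3, 671 and 672 without -/- control array 1 or 2, and 775 and 721 without -/- shTLS array 2 or 3. Cldn2, a tight junction protein, fell by 4.23 (SE 0.90, 18.8-fold, adjusted p = 0.0201). Hsd3b5, a male-biased steroid dehydrogenase, fell by 3.72, Cdc25b, a mitotic phosphatase, fell by 2.51 and Fjx1 fell by 2.36. Hsd3b5 and Fjx1 were above background on 1 of 3 +/+ shTLS arrays. Mrgprb3 fell as well (adjusted p = 0.0197), and since it was above background on 0 of 3 +/+ shTLS arrays no size is given. The largest rises were Sox12 (9.32, SE 0.94), Olfr738 (6.08), Xcr1 (5.94) and Asb7 (5.87), beside Fndc8 (adjusted p = 0.000203), which was above background on 1 of 6 control arrays. These are values of single probes. The other probe of Asb7, above background on 10 arrays, gave -1.13, and that of Xcr1 was above background on 0 arrays. Sox12 and Olfr738 had 1 tested probe each.

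Of 30 interferon response genes 9 rose over all genes and 14 adjusted over the list alone (median 1.08, 28 of 30 positive, adjusted p = 1.27e-07, and adjusted p = 0.588 with an estimated correlation). They included Rsad2 (2.45, SE 0.36, adjusted p = 0.00305), Isg15 (2.25), Eif2ak2 (1.46) and Gbp2 (1.31), the last pair not past the test when scaled to the spike-ins. In cholesterol synthesis 6 of 24 members fell and 10 adjusted over the list alone (median -0.47, adjusted p = 0.000361, and adjusted p = 0.535 with an estimated correlation). Srebf2 fell by 1.30 (SE 0.25, adjusted p = 0.0132) and Hsd17b7 by 0.98. The glutathione transferases Gsta4 and Mgst1 fell by 1.29 and 0.71 (list median -0.71, adjusted p = 0.000111, and adjusted p = 0.523 with an estimated correlation), and 5 members passed adjusted over the list alone. Agpat2 and Srebf1 fell by 0.81 and 0.75 (fatty acid synthesis median -0.52, adjusted p = 0.00479, and adjusted p = 0.165 with an estimated correlation). Txnrd2 fell by 1.06 (SE 0.19, adjusted p = 0.0101), the 1 antioxidant gene of 25 to do so, against 9 with the block. The antioxidant median was -0.30 (18 negative, adjusted p = 0.0223), a call lost with an estimated correlation (adjusted p = 0.523), with 75th percentile scaling (0.0945), with the spike-ins (0.0665) and without -/- control array 2 (0.0686) or -/- shTLS array 1 (0.0657). Bbc3, Polk and Plk2 of the p53 list rose by 0.93, 1.13 and 1.00, calls that ended when scaled to the spike-ins, where the list median of 0.35 was -0.43 (adjusted p = 0.0210, and adjusted p = 0.306 with an estimated correlation).

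The median of the stress response genes was 0.35, or -0.36 when scaled to the spike-ins (23 of 29 positive, adjusted p = 0.0329, and adjusted p = 0.685 with an estimated correlation). No member passed over all genes without the block, which gave 7 members higher and 1 lower. Of all 19018 genes the block gave 2915 higher and 2597 lower. Calr read 0.67 and Herpud1 0.62 (0.0210 and 0.0160 with the block), which were -0.056 and -0.050 when scaled to the spike-ins. The call was lost without +/+ control array 1 (0.0937), +/+ shTLS array 2 (0.0544) or 3 (0.0684), -/- control array 1 (0.0741) or -/- shTLS array 1 (0.0545). Hepatocyte identity genes had a median of -0.45 (25 of 29 negative, adjusted p = 0.0329, and adjusted p = 0.685 with an estimated correlation), and Cebpa and Ass1 fell by 1.06 and 0.65. That call was lost with 75th percentile scaling (0.0569), with the spike-ins (0.295) and without +/+ control array 1 (0.289), +/+ shTLS array 2 (0.0544), -/- control array 1 (0.0684) or -/- shTLS array 1 (0.0911). The block added calls for bile acid genes (adjusted p = 0.0368) and macrophage markers (0.0251), which gave 0.0609 and 0.0764 without it.

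Across genes the effects of shTLS in the 2 genotypes had a Pearson correlation of 0.884 and a Spearman correlation of 0.859, with 85.5% of genes on the same side of 0. Genes are not independent replicates, so no p is given. The 2 sets of effects share no array, and by replicate number the correlation was 0.816, 0.596 and 0.883. Of the called genes 157 were higher in both genotypes, 6 were lower in both, and 0 went opposite ways. Independent sets of calls would give 1.81 and 0.0139. The sets are not independent, since they share 1 fit with the same spread per gene, the slides and the vector, so these 2 numbers are no measure of chance here. With no filter on dim probes the correlation was 0.731.

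**Figure D3:**
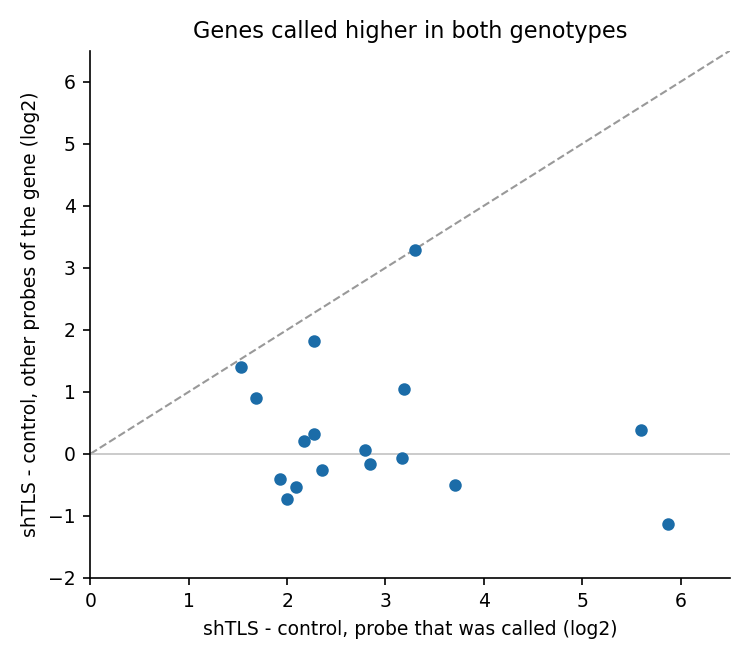
Log2 difference between shTLS and control, averaged over genotypes, for 17 genes called higher in both genotypes that have another probe well above background on at least 3 arrays: the called probe (horizontal axis) against the mean of the gene's other such probes (vertical axis). The dashed line marks equal values; the medians are 2.35 for called probes and 0.055 for the others.

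Whether the response to shTLS depends on PGC-1alpha was tested as the difference between both effects. With a preset correlation the list of interferon response genes passed, the fitted effect being larger in -/- cells in 26 of 30 members (median 0.50, adjusted p = 3.90e-06, and adjusted p = 0.961 with an estimated correlation). So did endothelial markers, 17 of 18 positive (median 0.43, adjusted p = 0.00114). Macrophage markers passed in the other direction, all 18 negative (median -0.56, adjusted p = 0.000183). No list passed with an estimated correlation (adjusted p = 0.961 for each). Irf7, a regulator of interferon genes, read 1.17, Dhx58 1.48 and Bst2 0.70. Among macrophage genes Lyz1, Lyz2 and Cd74 read -1.42, -1.33 and -1.07, and among endothelial genes Stab2 and Tek read 0.80 and 0.69. The interferon call was lost without +/+ control array 1 (0.225), +/+ shTLS array 3 (0.409) or -/- shTLS array 1 (0.739). Macrophage markers did not pass without +/+ control array 2 (0.0698) or 3 (0.0947), +/+ shTLS array 1 (0.146), -/- control array 1 (0.212) or 2 (0.270), or -/- shTLS array 3, where the median was 0.021 (0.529). Endothelial markers did not pass with no filter on dim probes (0.0606), without +/+ control array 3 (0.141), +/+ shTLS array 2 (0.448), -/- control array 2 (0.216) or 3 (0.274), or -/- shTLS array 1, where the median was -0.015 (0.902). Antioxidant genes had a median of 0.03, 15 of 25 positive (adjusted p = 0.611), and the other 21 lists gave adjusted p from 0.446 to 0.879.

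No single gene passed this test in limma, where 45 genes had an unadjusted p under 0.05, and none passed with either block (207 unadjusted with the replicate block). Leaving out 1 array gave 0 to 2 calls. The 10 genes with the smallest p, none of which passed (adjusted p = 1.0), were Xpnpep2 (3.58, SE 1.18), Kcnab2 (-1.49), Klf2 (1.18), Mark4 (1.02), S100a14 (-2.61), Cd74 (-1.07), and Gcg, which encodes glucagon, Sncg, Mmp24 and Klk1b27, for which no value is given since at least 1 group was not above background on any array. In simulated data of this design 0 of 100 genes with a 4-fold difference were recovered by this test, against 49 of 100 for shTLS in +/+ cells. The simulated noise was shared within mice only, so these shares may differ in the data. Ppargc1a gave -0.67.

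The absence of PGC-1alpha was compared with its presence in cells with the control hairpin. The fitted differences of macrophage and Kupffer cell markers were positive in all 18 members, and their median was higher in -/- cells in every pair (median 1.92, pairs 1.39, 4.25 and 0.33, adjusted p = 6.35e-10, and adjusted p = 0.957 with an estimated correlation). In the third pair Cd163 and Marco read lower in -/- cells. Circadian clock genes were lower in 17 of 18 members (median -0.53, pairs -0.43, -1.27 and -0.10, adjusted p = 0.000161), and gluconeogenesis genes in 12 of 14 (median -0.46, pairs -0.79, -0.56 and -0.22, adjusted p = 0.0226), both with an adjusted p = 0.957 with an estimated correlation. No member of these lists passed over all genes. Klk1b24, a kallikrein-related peptidase, was at least 16.2-fold higher in -/- cells, and Tff3, a secreted trefoil factor, was lower. In all 16 genes passed, 6 higher and 10 lower, and 617 had an unadjusted p under 0.05. With the block 30 passed, 12 higher and 18 lower.

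Klk1b24 had an adjusted p of 9.66e-05, and Rnase2a, an eosinophil-type ribonuclease above background on 2 of 3 +/+ arrays, rose by 4.55 (SE 0.66, adjusted p = 0.0364), a call lost with the mouse as a block (0.0598). Tff3 fell by 7.32 (SE 0.97, adjusted p = 0.0210), being above background on 1 of 3 -/- arrays. Ppp1r42 fell by 3.27, Bmp2k, a kinase, fell by 3.24 and Pop4, a subunit of RNase P, fell by 2.54 (SE 0.27, adjusted p = 0.00294). The other Bmp2k probes gave -0.34 averaged over vectors, and its call was lost with the mean of its probes. The calls of Klk1b24 and Pop4 held with each array left out in turn, and with only the groups compared 1 of the 6 held, that of Klk1b24.

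None of the lists passed with an estimated correlation (adjusted p = 0.957 for each). Cd5l, a Kupffer cell protein, read 2.97 (SE 1.38), Lyz1 1.94, Lyz2 1.80 and Cd74 0.83, none past the test. Macrophage medians per array were 8.82, 5.70 and 6.89 in +/+ and 10.6, 10.2 and 7.01 in -/- control cells. In the clock list Per1 read -0.92 (SE 0.43), Arntl -0.83 and Nfil3 -0.73, against 0.66 for Dbp. In gluconeogenesis G6pc, glucose-6-phosphatase, read -1.15 (SE 0.96), Tat -0.87, Pck2 -0.55 and Gpi1 -0.47. The gluconeogenesis call was lost with no filter on dim probes (0.0528), without +/+ control array 1 (0.805) and without -/- control array 3 (0.438). Cell cycle genes had a median of 0.47 with 22 of 28 positive (pairs -0.09, 1.53 and -0.07, adjusted p = 0.0359, and adjusted p = 0.957 with an estimated correlation), and Kif20a read 1.14, Cdc20 1.08, Aurka 0.83 and Bub1b 0.77. That call was lost with the block (0.142), 75th percentile scaling (0.0798), the spike-ins (0.155), and without +/+ control array 1 (0.0518) or 2 (0.835) or -/- control array 2 (0.119) or 3 (0.236). Stellate cell markers passed with the block (0.0109) and not without it (median 0.74, 0.137). Antioxidant genes had a median of 0.01, or -0.0028 with 75th percentile scaling, with 13 of 25 positive (pairs -0.18, 0.25 and -0.09, adjusted p = 0.875), and Mt1 read -0.80, Txnrd2 -0.46, Prdx2 0.47 and Gsr 0.30. The other 20 lists gave adjusted p from 0.0611 to 0.942.

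**Figure D4:**
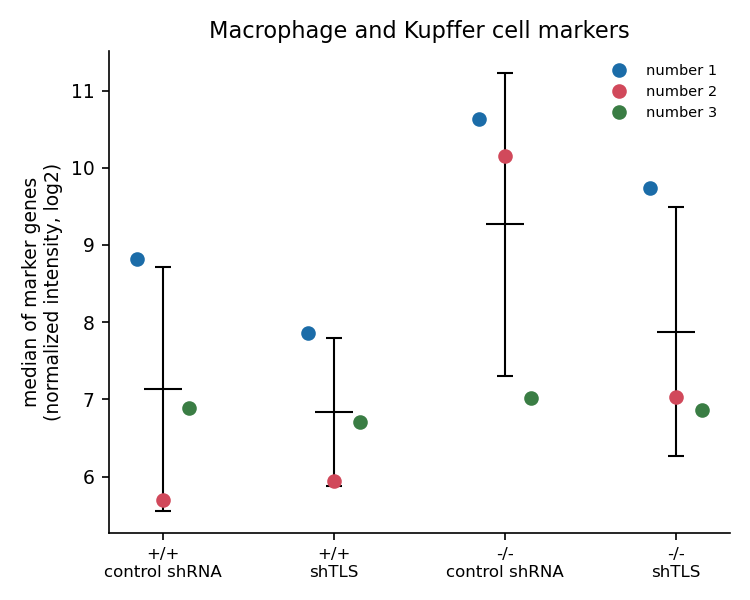
Median normalized log2 intensity over 18 macrophage and Kupffer cell markers on each array, by group (points, coloured by replicate number; lines are means and bars SD, n = 3). The control cells span 5.70 to 8.82 in +/+ and 7.01 to 10.6 in -/- mice.

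With shTLS, interferon response genes had positive fitted differences between -/- and +/+ cells in 28 of 30 members, and their median was higher in every pair (median 0.71, pairs 1.02, 0.89 and 0.60, adjusted p = 9.55e-09, and adjusted p = 0.834 with an estimated correlation). Differences were also positive for macrophage markers in 17 of 18 members (median 1.09, pairs 1.80, 0.99 and 0.22, adjusted p = 0.000891) and endothelial markers in 17 of 18 (median 0.90, pairs 1.75, 1.42 and -0.47, adjusted p = 2.91e-06), both with an adjusted p = 0.834 with an estimated correlation. Klk1b24 was at least 53.7-fold higher, Rnase2a at least 23.8-fold and Klk1b27 at least 3.82-fold. Tff3, above background on 1 of 3 -/- arrays, fell by 7.22 (SE 0.97, adjusted p = 0.0202), Pop4 fell by 2.42 (SE 0.27) and Zfp947, a zinc finger protein, fell by 1.89. In all 16 genes passed, 7 higher and 9 lower (402 with an unadjusted p under 0.05), and 32 with the block, 13 higher and 19 lower. Without +/+ shTLS array 1 the count was 10. Klk1b24, Klk1b27 and Pop4 held with each array left out in turn, and 4 of the 6 held with only the groups compared, not Pop4 (0.0751) and Zfp947 (0.285).

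No list passed with an estimated correlation (adjusted p = 0.834 for each). In the interferon list Oas2, above background on 1 of 3 +/+ arrays, read 2.93 (SE 1.43), Cxcl9 1.05, Psmb8 1.02 and Ddx58, the RNA sensor RIG-I, 1.01. Of the macrophage markers the complement genes C1qa and C1qc read 2.33 and 2.30, Marco 2.07 and Tyrobp 1.34, with C1qa above background on 2 of 3 +/+ arrays, and the call was lost without -/- shTLS array 1 (0.325). Of the endothelial markers Tie1, above background on 2 of 3 +/+ arrays, read 1.75, Fcgr2b 1.49, Oit3 1.27 and Tek 1.18, and the call was lost without that same array (0.0657). Clock genes were lower in 16 of 18 members (median -0.50, pairs -0.41, -0.86 and -0.06, adjusted p = 0.00316, and adjusted p = 0.834 with an estimated correlation), with Per1 at -0.66 and Cry2 at -0.65 against 0.82 for Dbp. Cytochromes of xenobiotic metabolism were lower in 23 of 29 members (median -0.30, pairs -1.01, -0.38 and -0.16, adjusted p = 0.00747, and adjusted p = 0.834 with an estimated correlation), with Cyp2b10 at -3.76 (SE 1.19), Cyp2b13 at -3.73 and Cyp2b9 at -3.25 against 1.75 for Cyp2a5. The clock call was lost without +/+ shTLS array 2 (0.280) or -/- shTLS array 1 (0.104), and the cytochrome call without the same arrays (0.360 and 0.843). Cell cycle genes had a median of 0.42, 21 of 28 positive (pairs 0.25, 0.37 and 0.06, adjusted p = 0.00760, and adjusted p = 0.834 with an estimated correlation), a call lost with the block (0.0694), the spike-ins (0.0569) and without +/+ shTLS array 1 (0.136) or -/- shTLS array 2 (0.319). Aurka read 1.00, Aurkb 0.89 and Top2a 0.78. Stellate cell markers had a median of 0.71, 15 of 17 positive (pairs 1.94, 0.27 and -0.56, adjusted p = 0.0248, and adjusted p = 0.834 with an estimated correlation), with Pdgfra at 1.34, Timp1 at 1.00 and Vim at 0.71. Their call was lost with the spike-ins (0.135), without +/+ shTLS array 3 (0.548), without -/- shTLS array 2 (0.0685) and without -/- shTLS array 1, where the median was -0.22 (0.401). Cholesterol synthesis passed with the block (0.0152) and not without it (0.115). Antioxidant genes had a median of 0.02, or -0.068 with 75th percentile scaling, 14 of 25 positive (pairs -0.12, 0.26 and 0.13, adjusted p = 0.679), and Prdx2 read 0.51, Gpx1 0.28 and Gsr 0.28. The other 17 lists gave adjusted p from 0.115 to 0.945.

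Averaged over both vectors, with the mouse as a random block, 22 genes differed between the genotypes, 10 higher and 12 lower in -/- cells (524 with an unadjusted p under 0.05). Without a block for the mouse 56 passed, and with the replicate block 138, 74 higher and 64 lower. Both of these fits count the arrays of a mouse as independent. In simulated data the replicate block gave 177 false calls of 300 here. Igsf23 rose by 3.95 (SE 0.51, adjusted p = 0.0124) and Atp2c1, a calcium pump of the Golgi, by 1.94, while its 2 other probes gave a mean of -0.054. Klk1b24, Klk1b27 and Rnase2a were higher too (adjusted p = 2.65e-05, 0.00514 and 0.0130), without a size since +/+ cells with shTLS were not above background on any array. Tff3, above background on 2 of 6 -/- arrays, fell by 7.27 (SE 0.76, adjusted p = 0.00231), Bmp2k by 3.17, Ppp1r42 by 2.64, Pop4 by 2.48 and Zfp947 by 1.80. Macrophage markers were higher in all 18 members (median 1.40, adjusted p = 3.24e-08) and interferon response genes in 28 of 30 (0.51, adjusted p = 8.91e-05), while clock genes were lower in 16 of 18 (-0.56, adjusted p = 0.000202) and gluconeogenesis genes in 13 of 14 (-0.32, adjusted p = 0.00342), each with an adjusted p = 0.800 with an estimated correlation. Cell cycle genes (0.48, adjusted p = 0.00105), endothelial markers (0.75, adjusted p = 0.00131), xenobiotic cytochromes (-0.25, adjusted p = 0.00342) and stellate cell markers (0.79, adjusted p = 0.0419) passed as well, the last not with 75th percentile scaling (0.0603), the deposited values (0.0541) or the spike-ins (0.168). With an estimated correlation the adjusted p was 0.800 for the first 3 of these and 0.886 for stellate cell markers. Cyp2b13, Cyp2b10 and Cyp2b9 read -4.08, -4.06 and -3.70, and Cyp2a5 1.46. They passed only with the replicate block (0.0353, 0.0294, 0.0287 and 0.0158), which leaves out the mouse, so these calls are not reliable. Antioxidant genes had a median of 0.04 (15 of 25 positive, adjusted p = 0.899), and cholesterol synthesis passed with the block alone (0.0373 against 0.281). Across genes the effects of genotype under both vectors, which share mice, had a Pearson correlation of 0.717 and a Spearman correlation of 0.665. Of the called genes 4 were higher and 7 lower under both.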

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

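The tests of other probes with signal, of probe sites that differ between the mice, of 1 culture low in macrophages and of a lower share of hepatocytes were chosen after the result was seen.

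Only the test of the difference between the effects of shTLS in both genotypes set results apart, and it did so for 3 gene lists. The fitted effects on interferon response genes were larger in -/- cells by a median of 0.50, while no single gene passed. Macrophage markers differed by a median of -0.56 and endothelial markers by 0.43. None of these passed with an estimated correlation (adjusted p = 0.961), and each was lost without 1 of several arrays, as the report gives.

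Counts of calls were compared with those of other splits of the same samples, over the 18930 genes without a missing value. With 10 splits of 6 arrays or mice a share under 0.05 cannot be had. For shTLS in +/+ cells 1 of the 10 gave as many genes, the real split with 229, and the highest other gave 6. In -/- cells this was 1 of 10, with 182 and 1, and for genotype with shTLS 1 of 10, with 16 and 1. For genotype with the control hairpin 2 of 10 gave as many, with 17 in the real split and 41 in another, and averaged over vectors 2 of 10, with 22 and 202. In both cases the other split set +/+ mouse 1 and -/- mice 1 and 2 against the rest, which points to a structure of the samples other than genotype. These mice also had the highest macrophage marker medians with either vector. With the control hairpin they read 8.82, 10.6 and 10.2, against 5.70 to 7.01 in the rest. With shTLS they read 7.86, 9.73 and 7.04, against 5.95 to 6.86. Whether this underlies the split was not tested. Among the 4 splits that part all 3 pairs, as the real one does, the highest other count was 0 in each of the 4 comparisons of single groups. For the difference of effects, where no gene passed, 7 of 10 splits gave as many genes at an unadjusted p under 0.05, with 44 in the real split and 1218 in another. For shTLS averaged over genotypes 1 of 100 drawn splits gave as many, the real one with 1542. This argues against chance without excluding it, since another drawn split came near. That split, the highest other, gave 1319, with number 2 on 1 side and number 3 on the other, which follows the slides. It parted number 1 by the real vectors. The count with the slide as a block was 5512. Of 32 ways of swapping the vectors within mice 1 gave as many, the real one, and the others gave 0.

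The first pattern is the 157 genes called higher with shTLS in both genotypes. With spike-in scaling the median change of these genes was 2.40, against 3.14 without it, and 107 were still called in both. The scaling moved the median of all genes by -0.77, so lower overall signal on the shTLS arrays is too small a shift to be the whole cause. With genes chosen for large rises this outcome was likely from the start. For 17 of them with another probe well above background on at least 3 arrays these other probes changed by a median of 0.055 (quartiles -0.41 and 0.90), while the called probes changed by 2.35, so a candidate explanation is that many of these probes bind another transcript, which may be one brought by the vector. Of these genes 4 (23.5%) had other probes that rose by over 1/2 as much, against 66.7% of 135 genes called higher in the average but not in both genotypes. A response to the loss of TLS and an effect of this vector apart from TLS cannot be told apart, since the series holds 1 vector against TLS.

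The second pattern is the 24 genes called between the genotypes, 10 of them named. Mice of different sexes are argued against, since the median difference of Xist and 4 Y-linked genes was 0.064, with Xist above background on all 12 arrays and the Y-linked genes on 0. Variants linked to the deleted locus stay open for Bmp2k, the 1 named gene that shares the chromosome of Ppargc1a. That number is too small to decide (0.656 expected by chance, exact one-sided hypergeometric p = 0.493). The rest of the named genes lie on other chromosomes, which argues against linkage to the deleted locus for them. Genes without a symbol were not placed on a chromosome, and variants at other loci were not tested. Probe sites that differ between the mice stay open as well. For 6 genes with another probe these changed by a median of 1.94 in the direction of the called probe (quartiles 0.576 and 2.65), against 2.81 for the called probes. The mean was -0.34 for the 2 other probes of Bmp2k and -0.054 for the 2 of Atp2c1. It was 4.39 for Igsf23, -1.29 for Pop4, and 2.58 and 2.67 for the 2 genes without a symbol. An effect of PGC-1alpha itself stays open and was not tested beyond the comparison.

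The third pattern is the higher level of macrophage markers in -/- cells with the control hairpin, 1.92 in the median (adjusted p = 0.957 with an estimated correlation). A single +/+ culture low in macrophages stays open as a cause: without the second +/+ control array the median was 1.27 (adjusted p = 1.59e-08, and adjusted p = 0.816 with an estimated correlation), and the 2 pairs left gave a mean of 0.86 with an SE of 0.53. The same mouse had the lowest marker median of the +/+ mice with shTLS too (5.95, against 7.86 and 6.71). A single +/+ mouse low in these markers therefore stays open as well. A lower share of hepatocytes cannot be told apart from more macrophages, since macrophage markers exceeded endothelial and stellate markers by 1.41 on average with an SE of 1.20 (pairs -0.038, 3.80 and 0.48). Deviations of the 18 markers from their group means correlated by a median of 0.583, above the highest of 1000 random lists of that size (0.267). Numbers of macrophages that vary between cultures would give this. So would any regulation that the markers share, since the random lists were drawn from all genes, and this test cannot tell these apart. A difference between genotypes in the number of macrophages stays open.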

How the results depend on the processing

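Scaling to the spike-in spots and the block without the arrays of 1 number were chosen after seeing the data. Signal over background limits the genes that can be compared: those dim in 1 group have a bound for a fold, and the filter on dim probes decides which are tested. Where a fit was left with 2 arrays in a group, or only the groups compared were used, fewer arrays stood behind the test. For the other differences the cause was not tested.

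For shTLS in +/+ cells 230 genes passed, and 355 with 75th percentile scaling, 133 with normexp, 109 with probes well above background on all arrays (fewer genes tested), 2408 with the replicate block (the slide block is the same), 2988 with the mouse block, 48 with only the groups compared and 3204 with spike-in scaling. With the block and without number 1, 2 or 3 the counts were 369, 810 and 445, and leaving out each array gave 112 to 320. For shTLS in -/- cells 183 passed, and 109 with normexp, 92 with the filter for all arrays, 1192 with the replicate or slide block, 1624 with the mouse block, 336 with the block and without number 1 (without number 2 or 3 not given here), and 94 to 224 with an array left out. Averaged over genotypes 1553 passed, and 999 with the filter for all arrays, 5512 with the replicate or slide block, 6253 with the mouse block, 9866 with spike-in scaling, 3626 with the block and without number 2 (without number 1 or 3 not given here), and 671 to 1967 with an array left out. For genotype with the control hairpin 16 passed, and 3 with the filter for all arrays, 30 with the replicate or slide block and 8 with only the groups compared. With shTLS 16 passed, and 2 with the filter for all arrays, 32 with the replicate or slide block and 10 to 15 with an array left out. Averaged over vectors 22 passed, and 6 with the filter for all arrays, 138 with the replicate or slide block and 56 without a block for the mouse. The last 2 of these fits count the arrays of a mouse as independent. The difference of effects had 0 calls in limma under each processing and block, and 0 to 2 with an array left out. With the block, 75th percentile scaling moved the share of calls that were higher from 59.7% to 72.2% in +/+ cells (7.29% with the spike-ins), from 70.1% to 79.8% in -/- cells (7.30%), and from 52.9% to 65.3% on average (7.44%).

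With an array left out Ppargc1a ran from -0.32 to 0.74 for genotype with the control hairpin, -0.95 to 0.32 with shTLS, and -0.34 to 0.068 averaged over vectors. For shTLS it ran from -0.73 to 0.69 in +/+ cells, -0.65 to 0.060 averaged over genotypes, and -1.25 to 0.16 for the difference of effects.

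With spike-in scaling the direction turned for Ppargc1a (-0.80) and Fas (-0.038) in +/+ cells, for Herpud1 (-0.055), Creld2 (-0.049) and Asns (-0.018) in -/- cells, and for Herpud1 (-0.050) and Calr (-0.056) averaged over genotypes. It also turned for the lists of interferon response (-0.13) and p53 targets (-0.40) in +/+ cells, of the stress response (-0.32) and p53 targets (-0.44) in -/- cells, and of both averaged over genotypes (-0.36 and -0.43). The construction shows the cause, since this scaling moved the median of all genes by -0.80, -0.74 and -0.77. Antioxidant genes between genotypes turned to -0.0028 with 75th percentile scaling and -0.053 with normexp (control hairpin), and to -0.068 with 75th percentile scaling (shTLS). With an array left out they ran from -0.11 to 0.16 and from -0.045 to 0.18. Left-out arrays also turned stellate cell markers with shTLS (-0.22 to 1.501) and, for the difference of effects, macrophage markers (-1.67 to 0.021) and endothelial markers (-0.015 to 0.86). The correlation of both shTLS effects was 0.731 with no filter on dim probes and 0.755 to 0.872 with an array left out.

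Of 5385 alternative values for named genes 4905 kept direction and side of the threshold, 338 lost the call, 130 gained it and 12 turned. Of 903 for lists 726 kept both, 161 lost the call and 16 turned. Genes and lists that were not called and stayed so count as kept, so these counts do not measure how stable the calls were. The block ended the calls of p53 targets in +/+ cells and of cell cycle genes between genotypes with either vector, 3 of 86 list values, and changed no other call of a list that passed. Of the named calls 11 of 18 in +/+ cells, 9 of 12 in -/- cells, 7 of 10 on average, 2 of 6 and 3 of 6 for genotype with each vector and 6 of 10 averaged over vectors held with each array left out. With only the groups compared 7 of 18, 10 of 12, 1 of 6 and 4 of 6 held in the 4 comparisons of single groups.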

Other observations

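Lists that did not pass as a group held called members for shTLS averaged over genotypes. Among RNA-binding proteins, Hnrnpa3 fell by 1.098 (SE 0.20, adjusted p = 0.00916), a call lost with the mean of its probes, and Srsf2, a splicing factor, rose by 1.02 (adjusted p = 0.0363), a call lost with spike-in scaling (list median 0.17, adjusted p = 0.153). Among xenobiotic genes Nr1i3, the nuclear receptor CAR, rose by 1.94 (SE 0.33, adjusted p = 0.00683) and Cyp2c55 by 2.21 (adjusted p = 0.00733), while Cyp2c70 fell by 1.88 (list median -0.52, adjusted p = 0.0609). In the cell cycle list the mitotic kinases Aurkb and Cdk1 fell by 1.93 and 0.94, and Mcm7 and Mcm4, subunits of the replicative helicase, rose by 0.85 and 0.71, calls lost with spike-in scaling (list median -0.58, adjusted p = 0.438). In fatty acid oxidation the dehydrogenases Acads and Hadh read -1.13 and -1.30 and passed (list median -0.29, adjusted p = 0.0609). Il6 rose by 3.22 (SE 0.46, adjusted p = 0.00249) in a list of inflammation genes with a median of -0.32 (adjusted p = 0.309). Single calls were Hsf1 and Hspb1 of the heat shock list (-0.83 and -0.84), Tfb2m, a mitochondrial transcription factor (1.18), and Spp1, osteopontin (-1.60).

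The lists of oxidative phosphorylation (median -0.10, adjusted p = 0.0609), bile acids (-0.58, 0.0609), gluconeogenesis (-0.27, 0.0828), the tricarboxylic acid cycle (-0.15, 0.218), haem metabolism (-0.12, 0.292), cholangiocyte markers (-0.80, 0.0834), macrophage markers (-0.72, 0.0764) and stellate cell markers (-0.31, 0.278) did not pass in that average. Nor did circadian clock genes (0.34, 0.278), endothelial markers (0.27, 0.379), regulators of mitochondrial biogenesis (0.06, 0.880) and heat shock chaperones (0.04, 0.970), whose medians were smaller than the shift of -0.77 in all genes under spike-in scaling. On the second principal component, with 21.7% of the variance, the second +/+ control array stood at -124.3 and +/+ shTLS array 2 at -73.0.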
